A study of Homo sapiens with 6 samples.

How the data were processed

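RNA was sequenced from LNCaP cells, an androgen-sensitive human prostate cancer line. The labels place 3 libraries in a group given dihydrotestosterone (DHT) at 1 nM and 3 in a group given the same DHT plus an extract of white button mushroom (WBM) at 3 µL/mL, both for 48 h. Groups were taken from the sample titles, and each column of the deposited table was matched to its library by the code in that title. The labels do not say whether the triplicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. No library without DHT was analysed here.

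The authors deposited raw read counts per gene, whole numbers with no normalization, together with each gene's position, strand and length. Per the submitters' processing notes, the tools involved were bcl2fastq 2.18.0.12, STAR 2.6.0, HTSeq 0.6.0 and edgeR 3.28.1, with hg19 as the genome build. The notes give the tools no role or order, and the annotation, the strand setting and any filter are not given in the sources used here. Coordinates are those of the deposited table, read as hg19. Without a known strand setting, reads from overlapping genes on opposite strands cannot be told apart. Reads that match near-identical copies, such as the AKR1C and UGT2B families or ribosomal protein genes and their pseudogenes, can be lost or credited to the wrong copy during counting, so values of single members of such families are uncertain.

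The table held 23354 genes, of which 4691 had no count in any library. Total counts were 21219828, 20304623 and 20813808 in DHT replicates 1 to 3 and 20138485, 19127357 and 21490953 in DHT+WBM replicates 1 to 3. Between 16511 and 16720 genes were detected per library, and the 10 most abundant genes took 2.68 to 2.92% of the counts. LYZ, at 2.10 CPM (counts scaled to a common library total) in DHT, rested on 129 counts over 3 libraries, so genes near 1 CPM have wider errors than abundant ones.

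Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 in at least 3 libraries and a minimum total count of 15, which left 13466 genes. Library sizes were scaled by TMM factors of 0.979 to 1.02. The quasi-likelihood F-test compared DHT+WBM with DHT with no other covariate, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. Genes with an adjusted p under 0.05 are described as higher or lower. Log2 fold changes are DHT+WBM over DHT, with standard errors (SE), and levels are TMM-normalised CPM as mean ± SD over 3 libraries.

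The test, the named-gene rule, 29 gene lists and the alternatives were fixed before the data were examined. Named genes were 8 focal genes of the androgen axis, the 6 largest rises and 6 largest falls among genes past the test with a mean of at least 5 CPM and no overlap between the groups' libraries, and up to 3 members with the smallest adjusted p from each list past its set test or with at least 3 changed members. Other genes are named as examples of a list's makeup or as exceptions to its direction, and were chosen after their values were seen. Some genes that the rule names are not reported here. Members were matched by symbol, and CCN3 was found under its synonym NOV. The list of mitochondrially encoded genes matched no symbol and is not analysed here. The other 28 lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, and adjusted over these 28 lists. Some lists share members, so their tests are not independent of each other.

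The alternatives were RLE factors, upper-quartile factors, library totals only, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p under 0.01, a minimum change of 2-fold, Y-linked genes left out, and each library left out in turn. Named genes were refitted under these settings at the same threshold. The lists were run with RLE factors, the 1 CPM filter, the block and each library left out, and also with an estimated correlation in camera and with the fry test. Transcript GC content came from GENCODE transcripts of GRCh38 and was used only to fit a loess trend of the log2 fold changes on GC and length. It was found for 98.7% of the tested genes.

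The fit was tested on simulated counts of DHT+WBM against DHT drawn from the real means and library sizes, over 13372 genes. It called 57.1% of genes simulated with a log2 change of 0.25, 86% at 0.5, 96% at 1 and 100% at 2. Of the unchanged genes, 0.099% were called. Unchanged genes made up 13134 of the 13372, whereas 58.2% of genes were called in the real comparison. The adjusted p depends on the share of changed genes, so these rates need not carry over to the real comparison. A simulated list of 40 genes shifted by -0.4 passed the set test, and 0 of 27 unshifted lists did. Simulated genes were drawn independently, whereas correlations estimated in the real lists ran as high as 0.53, for cytosolic ribosomal proteins. The simulation therefore cannot show whether the preset correlation holds for the real lists.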

Results

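Gene expression was measured by RNA sequencing in LNCaP cells, a human prostate cancer line whose growth responds to androgens, after 48 h with DHT at 1 nM. DHT is a potent natural androgen. In 3 libraries the cells also received WBM extract, made from the food mushroom Agaricus bisporus, and in 3 they did not. The labels do not say whether the cells without extract received a vehicle in its place. The libraries held between 19127357 and 21490953 counts each. The study asked whether the extract disturbs androgen signalling, and the single comparison its design gives is DHT+WBM against DHT.

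The extract was accompanied by a broad shift in expression. Most measured members of the androgen-induced list, such as KLK3, which encodes prostate-specific antigen, were lower in DHT+WBM, and so were most of the cell division, endoplasmic reticulum unfolded protein response and interferon lists. Most measured members of the NRF2, aryl hydrocarbon receptor and NF-kB lists were higher. These lists passed the camera set test with a preset correlation, and none of the 28 lists passed with an estimated correlation, where the lowest adjusted p was 0.135. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3928 of 13466 genes were higher and 3909 were lower. These calls covered 58.2% of the tested genes, and 440 of the rises and 328 of the falls were at least 2-fold. Beyond counting noise, the common coefficient of variation between libraries of a group was 3.39%, a spread that may be technical. The share of genes called therefore reflects this small spread as well as the size of the changes. Of all tested genes, called or not, 62.2% had the 3 libraries of one group entirely above those of the other, where chance gives 10%. The first principal component carried 77.7% of the variance and separated the groups, while the next carried 6.71%.

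Among the focal genes of the androgen axis reported here, KLK3 showed the largest fall. KLK3 (chromosome 19, 51358171 to 51364020, plus strand, hg19) went from 1683 ± 75.4 CPM in DHT to 617 ± 6.25 CPM in DHT+WBM (SD, n = 3), a log2 fold change of -1.45 ± 0.04 (SE, edgeR adjusted p = 3.92e-28). Its neighbour KLK2 (chromosome 19, 51376689 to 51383823), a related kallikrein, went from 335 ± 19 to 142 ± 4.08 CPM, a log2 fold change of -1.24 ± 0.04 (edgeR adjusted p = 4.20e-25). The membrane protease gene TMPRSS2 (chromosome 21, 42836478 to 42903043) fell from 185 ± 10.3 to 107 ± 1.88 CPM, a log2 fold change of -0.79 ± 0.04.

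Other focal genes were higher with the extract. FKBP5 (chromosome 6, 35541362 to 35696397), a co-chaperone gene that both androgens and glucocorticoids induce, was 915 ± 14 CPM against 842 ± 70.5 CPM, a log2 fold change of 0.12 ± 0.04 (edgeR adjusted p = 0.0153). The libraries of the groups overlapped for FKBP5, alone among the 78 named genes. Its call was lost without DHT replicate 1, with a log2 fold change of 0.07 (edgeR adjusted p = 0.159), and without DHT+WBM replicate 1, with 0.10 (edgeR adjusted p = 0.106). SRD5A1 (chromosome 5, 6633500 to 6669675), a 5-alpha-reductase that makes DHT from testosterone, rose from 36.5 ± 1.33 to 44.1 ± 1.48 CPM. AKR1C3 (chromosome 10, 5005454 to 5149878), a 17-ketosteroid reductase, rose from 2.91 ± 0.51 to 37.9 ± 2.0 CPM, a log2 fold change of 3.70 ± 0.09.

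**Figure D1:**
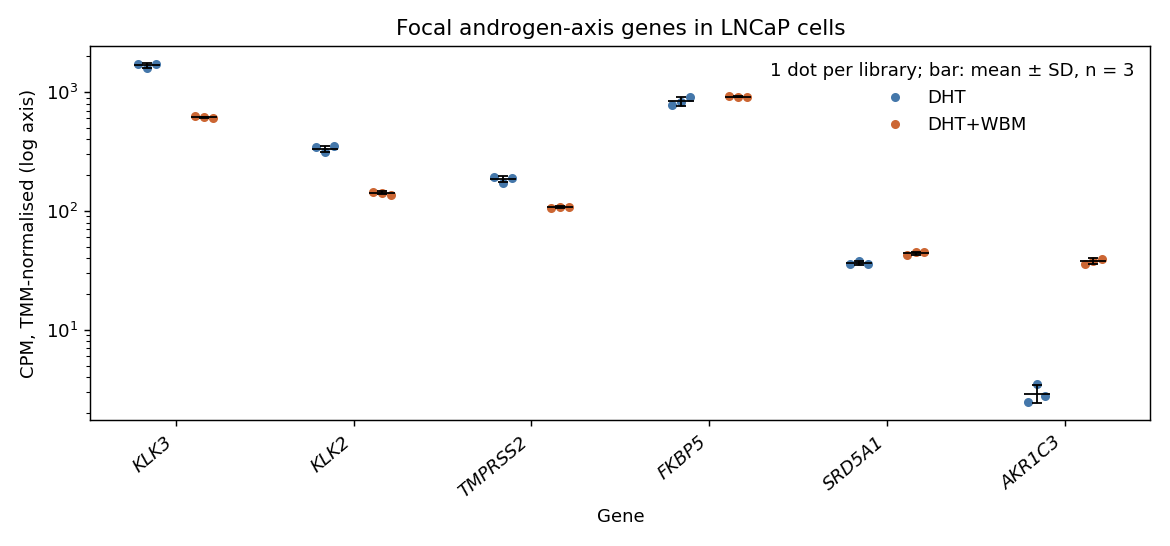
Levels of 6 focal androgen-axis genes in LNCaP cells, in TMM-normalised CPM on a log axis, with 1 dot per library and bars for mean ± SD (n = 3) in DHT (blue) and DHT+WBM (orange). KLK3, KLK2 and TMPRSS2 sat lower in DHT+WBM, SRD5A1 and AKR1C3 sat higher, and FKBP5 was the gene whose libraries overlapped.

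The androgen-induced list moved down as a group. Of its 40 measured members, 31 fell, 3 rose and 6 did not pass the test, with a median log2 fold change of -0.44. CHRNA2, a nicotinic receptor subunit gene, fell from 45.9 ± 2.89 to 16.1 ± 0.77 CPM. The exceptions were SGK1, a serum- and glucocorticoid-regulated kinase gene, with a log2 fold change of 0.72, the kallikrein gene KLK4 with 0.25, and FKBP5. The camera test gave an adjusted p of 5.88e-09 against all other genes, and an adjusted p of 0.181 with an estimated correlation.

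The androgen-repressed list moved the opposite way, with 9 of 11 measured members higher and a median log2 fold change of 0.62 (camera adjusted p = 0.00879, and adjusted p = 0.248 with an estimated correlation). CLU, a secreted chaperone gene, rose 1.96-fold, from 90.2 ± 3.91 to 177 ± 2.01 CPM. UGT2B15, which glucuronidates DHT, rose 1.76-fold to 65.7 ± 4.0 CPM, although UGT2B genes share sequence and the split between them is uncertain. Of the 2 members that fell, DDC, the aromatic amino acid decarboxylase gene, went from 18.4 ± 0.16 to 6.69 ± 1.06 CPM. Both lists take their direction from general knowledge of androgen action, since no library without DHT was analysed here.

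Genes of androgen metabolism and conjugation were mostly higher. Of 18 measured members, 12 rose, 1 fell and 5 did not pass the test, with a median log2 fold change of 0.49 (camera adjusted p = 1.95e-05, and adjusted p = 0.135 with an estimated correlation). AKR1C1 and AKR1C2, which reduce DHT and other ketosteroids, rose by log2 fold changes of 4.59 ± 0.08 and 4.61 ± 0.08 from levels of 2.73 ± 0.19 and 2.55 ± 0.19 CPM in DHT. Because the AKR1C genes are nearly identical and their annotated spans overlap, their reads were also summed. The sum of AKR1C1, AKR1C2 and AKR1C3 went from 8.19 ± 0.88 to 166 ± 4.62 CPM, a 20.3-fold rise. The member that fell was STS, the steroid sulfatase gene, with a log2 fold change of -0.57.

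Cofactors and chaperones of androgen signalling leaned lower, with 11 of 18 members lower, 2 higher and a median log2 fold change of -0.14 (camera adjusted p = 0.0285, and adjusted p = 0.181 with an estimated correlation). HOXB13 and GATA2, transcription factors of prostate epithelium, were 1.42-fold and 1.39-fold lower. HSP90AB1, which encodes a chaperone of steroid receptors, fell from 2112 ± 41.6 to 1550 ± 25.3 CPM. Of the luminal prostate markers, 7 of 15 were lower and 2 higher, with a median log2 fold change of -0.28 (camera adjusted p = 0.0168, and adjusted p = 0.181 with an estimated correlation). That list shares members such as KLK3 and KLK2 with the androgen-induced list, and its epithelial members EPCAM, CDH1 and KRT18 did not pass the test, with log2 fold changes of -0.04, 0.07 and 0.01.

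Among genes past the test with a mean of at least 5 CPM and no overlap between the groups, OASL showed the largest fall and AKR1C2 the largest rise. OASL (chromosome 12, 121458095 to 121477045), an oligoadenylate synthetase-like interferon-induced gene, was 21.5-fold lower, at 5.81 ± 0.21 CPM against 125 ± 10.8 CPM. IFIT2 (chromosome 10, 91061706 to 91069033), which encodes an interferon-induced tetratricopeptide repeat protein, was 17.2-fold lower, at 8.98 ± 0.78 CPM against 155 ± 11.4 CPM. RSAD2, the gene of the antiviral enzyme viperin, IFIT1 and IFIT3 followed, with log2 fold changes of -3.25 ± 0.14, -2.99 ± 0.09 and -2.38 ± 0.07. The dynein heavy chain gene DNAH8 completed the largest falls, at 2.16 ± 0.71 CPM against 10.7 ± 0.74 CPM. Among the largest rises, after the AKR1C genes, CYP1A1 (chromosome 15, 75011883 to 75017877), a cytochrome P450 that metabolises aromatic compounds, rose 7.66-fold to 41.9 ± 4.04 CPM. SERPINB7, a protease inhibitor gene, rose 6.21-fold from 1.96 ± 0.57 CPM, and HMOX1, the heme oxygenase gene, rose 5.71-fold to 102 ± 2.72 CPM. The IFIT genes lie inside the span of LIPA on the opposite strand, so a share of their reads could belong to that gene if counting ignored strand.

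**Figure D2:**
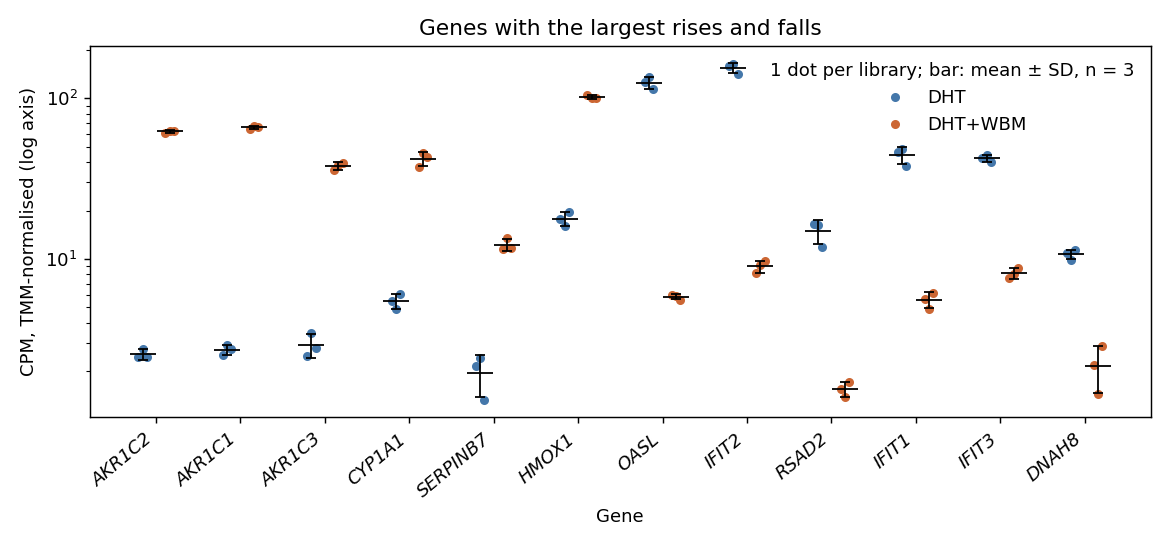
Levels of the 6 genes with the largest rises and the 6 with the largest falls, in TMM-normalised CPM on a log axis, with 1 dot per library and bars for mean ± SD (n = 3) in DHT (blue) and DHT+WBM (orange). Genes were chosen for no overlap between the groups, and OASL was near 125 CPM in DHT and 5.81 CPM in DHT+WBM.

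Across the interferon response list, 13 of 19 measured members were lower, 2 were higher and 4 did not pass the test, with a median log2 fold change of -0.51 (camera adjusted p = 0.000225, and adjusted p = 0.249 with an estimated correlation). The RNA sensor gene DDX58 and the chemokine gene CXCL10 fell with log2 fold changes of -0.91 and -0.74. The members that rose were IFI27, at 0.80 from a level near 1 CPM, and IRF7, at 0.24.

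The NF-kB and inflammation list moved in the other direction from the interferon list, with 14 of 15 measured members higher and a median log2 fold change of 0.84 (camera adjusted p = 5.54e-06, and adjusted p = 0.135 with an estimated correlation). TNF, the tumour necrosis factor gene, rose 3.70-fold, from 5.04 ± 0.06 to 18.6 ± 1.01 CPM. TNFAIP3, an inhibitor of NF-kB signalling that NF-kB itself induces, rose 2.09-fold to 58.1 ± 1.00 CPM. CLEC7A, which encodes the beta-glucan receptor dectin-1, rose 1.97-fold, from 75.8 ± 1.47 to 149 ± 2.92 CPM. The chemokine gene CCL2 was the member that fell, with a log2 fold change of -0.24.

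Among NRF2 targets, which encode antioxidant and iron-handling proteins, 17 of 20 measured members rose, 2 fell and 1 did not pass the test, with a median log2 fold change of 0.82 (camera adjusted p = 1.23e-08, and adjusted p = 0.135 with an estimated correlation). NQO1, a quinone reductase gene, rose 3.71-fold, from 245 ± 13.2 to 911 ± 15.6 CPM. The ferritin heavy chain gene FTH1 and the glutathione synthesis gene GCLM rose by log2 fold changes of 1.81 and 1.54. GCLC, the catalytic partner of GCLM, and the transporter gene ABCC1 fell, with log2 fold changes of -0.16 and -0.15, and the cystine transporter gene SLC7A11 did not pass the test, at 0.02. Targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, rose in 8 of 10 measured members, with a median log2 fold change of 1.5 (camera adjusted p = 0.000225, and adjusted p = 0.135 with an estimated correlation). TIPARP, a feedback repressor of that receptor, rose 1.95-fold to 63.3 ± 2.96 CPM, while the amino acid transporter gene SLC7A5 fell with a log2 fold change of -0.61. AHRR did not pass the test, at 0.56 (edgeR adjusted p = 0.169). Of the 8 that rose, CYP1A2, ALDH3A1 and UGT1A6 were rare in DHT, at 0.70, 0.31 and 0.05 CPM, and NQO1 is also in the NRF2 list.

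Cell cycle genes fell together. All 24 measured members of the G2/M and mitosis list were lower, with a median log2 fold change of -1.31 (camera adjusted p = 4.56e-16, and adjusted p = 0.135 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 94.1 ± 4.19 to 28.3 ± 2.07 CPM, BIRC5, the gene of survivin, from 119 ± 1.74 to 41.3 ± 0.96 CPM, and HMMR, a mitotic spindle gene, from 127 ± 5.45 to 45.9 ± 0.65 CPM. All 25 members of the DNA replication and G1/S list were lower as well, with a median log2 fold change of -1.02 (camera adjusted p = 1.99e-14, and adjusted p = 0.135 with an estimated correlation). The replicative helicase genes MCM2 and MCM4 were 2.27-fold and 2.13-fold lower, and CDC6, which loads the helicase, was 2.42-fold lower. Replication-dependent histones were mixed, with 5 of 11 measured members lower and 4 higher (camera adjusted p = 0.450, median log2 fold change -0.14). HIST1H2BK and HIST1H2BJ fell, with log2 fold changes of -0.64 and -1.28, and HIST1H1C rose, with 0.26.

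The p53 target list was higher in 14 of 20 members and lower in 3, with a median log2 fold change of 0.33 (camera adjusted p = 0.00345, and adjusted p = 0.181 with an estimated correlation). CDKN1A, the gene of the cyclin-dependent kinase inhibitor p21, rose 2.36-fold, from 109 ± 4.41 to 256 ± 1.87 CPM. TP53I3 rose 2.37-fold and TP53INP1 1.29-fold, while MDM2, the ubiquitin ligase of p53, did not pass the test, at 322 CPM against 315 CPM. Apoptosis regulators were mixed, with 10 of 21 higher and 5 lower (camera adjusted p = 0.366, median log2 fold change 0.14). The anti-apoptotic gene BIRC3 rose with a log2 fold change of 0.84, and the pro-apoptotic genes BCL2L11 and PMAIP1 fell, with -0.35 and -0.60.

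In the endoplasmic reticulum unfolded protein response list 18 of 20 members fell and 0 rose, with a median log2 fold change of -0.55 (camera adjusted p = 1.66e-08, and adjusted p = 0.181 with an estimated correlation). The chaperone genes HYOU1 and HSP90B1 and the disulfide isomerase gene PDIA4 were 1.69-fold, 1.67-fold and 1.66-fold lower. Cytosolic ribosomal protein genes fell in 27 of 30 members, with a median log2 fold change of -0.31 (camera adjusted p = 2.07e-09, and adjusted p = 0.262 with an estimated correlation). RPL23, RPL7A and RPL10A fell with log2 fold changes of -0.60, -0.51 and -0.45, and reads of such genes can be shared with their processed pseudogenes. The heat shock list had 8 of 15 members lower and 2 higher (camera adjusted p = 0.0944, median log2 fold change -0.12), among them HSPA8 with a log2 fold change of -0.41 and HSPB8 with 0.73.

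The integrated stress response list, whose members are induced by the factor ATF4, was mixed, with 10 of 24 higher and 8 lower (camera adjusted p = 0.491, median log2 fold change 0.09). GDF15, a secreted stress cytokine gene, rose 3.01-fold, from 134 ± 7.72 to 404 ± 8.74 CPM, and DDIT4 and ATF3 rose 1.63-fold and 1.84-fold. ATF4 itself fell, with a log2 fold change of -0.37. The hypoxia and glycolysis list had 12 of 19 members higher and 5 lower (camera adjusted p = 0.102, median log2 fold change 0.18), with VEGFA and ALDOA higher by log2 fold changes of 0.80 and 0.52 and the glucose transporter gene SLC2A1 lower at -0.49. For every list, the counts adjusted over the list alone equalled those over all genes tested, except that 6 hypoxia and glycolysis members were then lower. Of 6 metallothionein and metal response genes, 3 fell and 2 rose (camera adjusted p = 0.366, median log2 fold change -0.26), with MT2A at -1.20, MT1X at -0.51 and the zinc exporter gene SLC30A1 at 0.24.

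Lipid gene lists had median log2 fold changes between 0.11 and 0.27. In the cholesterol synthesis list 10 of 24 members rose and 3 fell, with a median log2 fold change of 0.11 (camera adjusted p = 0.0285, and adjusted p = 0.454 with an estimated correlation). The counts depended on scaling, with 13 higher and 2 lower under upper-quartile factors, and 16 higher and 2 lower under library totals alone. INSIG1, a sterol-responsive regulator, rose 1.75-fold, and FDFT1 and TM7SF2, enzymes of the pathway, rose 1.44-fold and 1.48-fold, although TM7SF2 overlaps VPS51. This call was lost without DHT replicate 2, DHT+WBM replicate 1 or DHT+WBM replicate 3, where the camera adjusted p was 0.0762, 0.0710 and 0.0845. Fatty acid synthesis genes were mixed, with 9 of 18 higher and 6 lower (camera adjusted p = 0.366, median log2 fold change 0.14). The NADPH-producing enzyme gene ME1 rose with a log2 fold change of 0.81, and the elongase gene ELOVL7 and the regulator SREBF1 fell, with -0.76 and -0.75. PPAR targets and fatty acid oxidation genes rose in 10 of 16 members and fell in 3, with a median log2 fold change of 0.27 (camera adjusted p = 0.0313, and adjusted p = 0.248 with an estimated correlation). EHHADH, a peroxisomal enzyme gene, rose 2.25-fold, while the acyl-CoA dehydrogenase gene ACADL fell with a log2 fold change of -0.67. Under a filter of at least 1 CPM in at least 3 libraries the camera adjusted p of this list was 0.0501.

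Polyamine genes split evenly, with 4 of 12 members higher and 4 lower (camera adjusted p = 0.950). The median log2 fold change of this list was 0.08, whereas its mean was -0.14 and the test pointed down. ARG2, an arginase gene that overlaps VTI1B, and SMS, the spermine synthase gene, were 2.70-fold and 2.0-fold lower, and the antizyme gene OAZ2 was 1.36-fold higher. Neuroendocrine markers were measured for 6 genes, of which 2 rose and 1 fell (camera adjusted p = 0.458, median log2 fold change 0.20). The enolase gene ENO2 rose from 6.59 ± 0.30 to 16.4 ± 2.32 CPM, SYT4 fell from 1436 ± 31.2 to 1075 ± 40.8 CPM, and the tubulin gene TUBB3 had a log2 fold change of 0.18 ± 0.06 (edgeR adjusted p = 0.00947). The TUBB3 call was lost in DESeq2 (adjusted p = 0.0502), without DHT replicate 2 (edgeR adjusted p = 0.0651) and without DHT+WBM replicate 1 (edgeR adjusted p = 0.112).

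Markers of other cell types were sparse. Of 3 measured basal epithelial markers, ITGA6 fell and DST rose, with log2 fold changes of -0.35 and 0.40 (camera adjusted p = 0.884, median -0.07). Of 6 fibroblast and smooth muscle markers, COL3A1 fell with a log2 fold change of -0.89 and the other 5 did not pass the test (camera adjusted p = 0.450, median -0.21). Of the 13 blood and immune cell markers, 2 were measured and both rose, CD68 with a log2 fold change of 1.88 and LYZ with 0.45 (camera adjusted p = 0.0621, median 1.16). That camera adjusted p was 0.0336 without DHT+WBM replicate 2. CD68 went from 23.0 to 84.5 CPM, while 7 other macrophage transcripts summed to 2.46 CPM in DHT and 3.06 CPM in DHT+WBM. LYZ alone made up 2.10 CPM of that sum in DHT and 2.86 CPM in DHT+WBM.

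**Figure D3:**
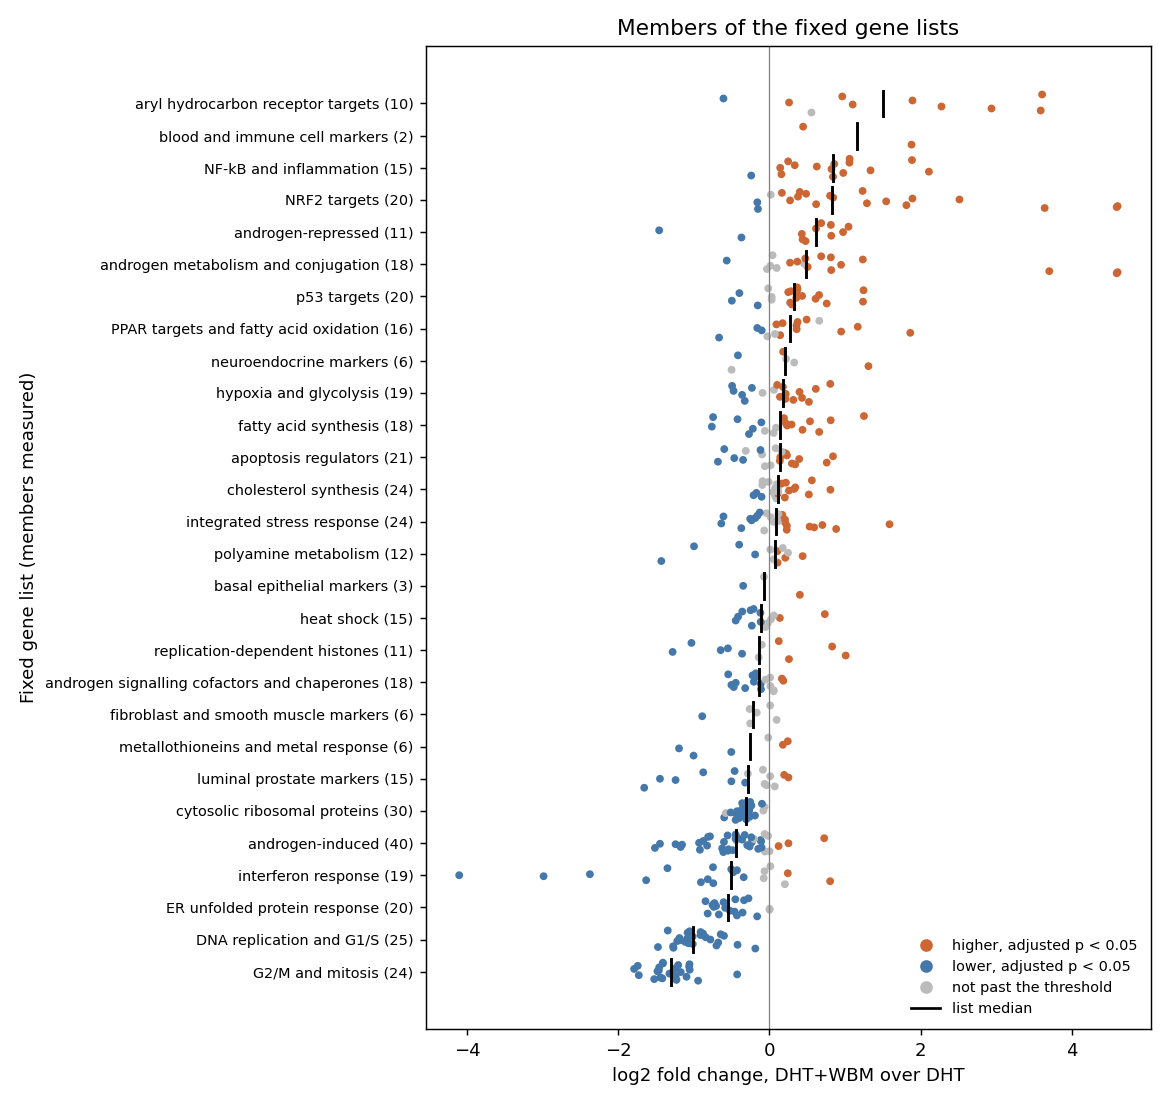
Log2 fold change (DHT+WBM over DHT) of every measured member of the 28 fixed gene lists, with 1 dot per gene coloured by the edgeR test (orange higher, blue lower, grey not past the threshold) and a black bar at each list's median. The G2/M and DNA replication lists lie wholly below 0, with medians of -1.31 and -1.02, and the aryl hydrocarbon receptor and NRF2 lists have medians of 1.5 and 0.82.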

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

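With a minimum change of 2-fold, 440 genes were higher and 328 lower. The other 32 recounts stayed within 1.5 times of 3928 higher and 3909 lower: DESeq2 gave 3134 and 3356, library totals alone 4675 and 3200, and leaving out 1 library 3440 to 3791 and 3642 to 3789. DESeq2 kept 81.8% of the calls, and 0 went in the opposite direction under any recount. The even split of the calls depended on scaling. The share that was higher was 50.1% with TMM factors, 56.5% with upper-quartile factors and 59.4% with library totals alone. Against TMM, the latter scalings shifted log2 fold changes by medians of 0.03 and 0.05, so calls of small changes depend on scaling too. With an estimated correlation, camera's adjusted p was 0.181 for the androgen-induced list and 0.248 for the androgen-repressed list. Their other alternatives ran from 3.99e-09 to 0.000105 and from 0.00047 to 0.0127. No list that passed camera with the preset correlation passed with an estimated one, and the cause was not tested. Among the list tests, 276 kept their side of the threshold, 20 lost it and 12 gained it, 11 of these under fry, which does not compare a list with other genes. Among refits of named genes, 1165 kept their call and 5, of FKBP5 and TUBB3, lost it. The median of every list kept its sign under the 3 other scalings.

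The replicate number as a replicate block gave 4079 higher and 4030 lower genes and kept 99.9% of the calls. It ended or added no call of a list or named gene. Deviations of same-numbered libraries correlated at 0.002, 0.26 and -0.03 across genes, and not every library correlated best with its own number. The values show no steady pairing by number. They cannot exclude pairing, since deviations were taken from the means of only 3 libraries per group. Depth limits small changes of genes near 1 CPM most. No mitochondrially encoded symbol was matched, so that exclusion removed Y-linked genes alone.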

Other observations

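The tests on division-linked members, on paralogs, on low counts, on the size of the CD68 rise and with MT2A kept were chosen after the results were seen, and the lists below were chosen after CD68, ETV5, SGK1, FKBP5 and MT2A had drawn attention. Lysosomal genes were higher with the extract. Of 30 measured lysosomal genes, none of them in the lists above, 20 rose, 1 fell and 9 did not pass the test, with a median log2 fold change of 0.20 (camera adjusted p = 9.66e-06, and adjusted p = 0.169 with an estimated correlation). The median lay above 100% of 10000 random lists matched on expression. Genes of the random lists, here and below, were drawn one by one. These percentiles therefore ignore correlation between list members and the spread between libraries. CD68, a lysosomal membrane protein gene, rose by 1.88, which is 6.46 SDs of these genes above their median and above the highest of them, SQSTM1 with 1.15, an autophagy receptor gene that NRF2 also induces. A wider rise of lysosomal genes may account for part of the CD68 rise, as a hypothesis from the same libraries. CD68 had drawn attention before the list was chosen, and members of a list need not move equally. Its distance from the other genes therefore cannot decide how much of its rise they would explain, and this stays open.

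SGK1 and FKBP5 rose while most androgen-induced genes fell, and both are also glucocorticoid targets. Among 11 other glucocorticoid-induced genes, with MT2A left out, 7 rose and 2 fell, with a median log2 fold change of 0.25, above 98.7% of random lists (camera adjusted p = 0.0400, and adjusted p = 0.169 with an estimated correlation). MT2A, also a glucocorticoid target, fell with -1.20, and with it kept the median of the 12 was 0.20, above 96.5% of random lists and under the bar of 0.21 set from them (camera adjusted p = 0.0989, and adjusted p = 0.266 with an estimated correlation). BCL6 and CEBPD rose by 0.63 and 0.53, whereas PER1 and ZBTB16 fell, with -0.43 and -0.28, so a wider rise of glucocorticoid-induced genes was not established and stays open. The list shares ANGPTL4 with the PPAR list, and FKBP5 was not called without DHT replicate 1 (0.07) or DHT+WBM replicate 1 (0.10). ETV5 rose with a log2 fold change of 1.66, but 15 ERK feedback genes had a median of 0.094, above 73.6% of random lists, with 8 higher and 2 lower (camera adjusted p = 0.0400, and adjusted p = 0.169 with an estimated correlation). For them a wider rise cannot be told apart from a few large ones such as ETV4 and IER3, at 1.78 and 1.61.

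The fall of androgen-induced genes did not follow transcript GC or length: with that trend removed the list's median was -0.43 (camera adjusted p = 9.35e-09, and adjusted p = 0.180 with an estimated correlation), where the trend itself had an SD of 0.029 over genes. Fewer dividing cells stay open as an explanation. Without CENPN and MPHOSPH9, which are tied to division, the median of the other 38 was -0.43 (camera adjusted p = 1.93e-08, and adjusted p = 0.187 with an estimated correlation), but leaving out 2 of 40 members can hardly move a median, and division may also act on the rest. The extract is the only difference between the groups that the labels give, and fewer dividing cells could also follow from it. Whether the extract acts directly on androgen signalling stays open, as a hypothesis with no separate test.

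The rise of NRF2 targets did not rest on reads shared between the AKR1C and AKR1B10 paralogs. Without AKR1C1, AKR1C2 and AKR1B10 the median of the other 17 members was 0.62, with 14 higher (camera adjusted p = 1.07e-06, and adjusted p = 0.181 with an estimated correlation). With the GC and length trend removed the list's median was 0.80 (camera adjusted p = 1.04e-08, and adjusted p = 0.133 with an estimated correlation). An NRF2 response to the extract is a hypothesis that may account for it. NFE2L2, the NRF2 gene, rose by 0.26 and its inhibitor KEAP1 did not pass the test, at 0.03, which leaves protein activity unmeasured.

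The fall of interferon-induced genes was not limited to rare transcripts. Among the 11 members with a mean of at least 10 CPM over all 6 libraries, the median was -0.75 and 9 were lower. IFIT1, IFIT2 and IFIT3 met that bar through their DHT levels, and were at 5.55, 8.98 and 8.12 CPM in DHT+WBM. Their falls were already known, so this count is no independent support. After removal of the GC and length trend the list's median was -0.49 (camera adjusted p = 0.000257, and adjusted p = 0.253 with an estimated correlation). DDX60, outside the list, fell from 74.0 to 15.7 CPM, while IRF1 and IRF3, interferon regulatory factor genes also outside it, rose by 0.52 and 0.15, and STAT2, a signal transducer of interferon receptors, did not pass the test, at -0.01. A lower antiviral response with the extract may account for it, as a hypothesis found in these same libraries.

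The 6 libraries can be divided into 3 and 3 in 10 ways. By edgeR's test the real division gave 7837 calls, the highest of the others gave 0, and 1 of the 10, the real one, gave as many. Each other division mixes DHT and DHT+WBM libraries, so the group difference widens the spread within its sides and lowers its calls. The 0 is therefore not a count expected by chance. The 10 divisions are also too few for a share under 0.05.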
